A study of Mus musculus with 5 samples.

How the data were processed

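Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in C2C12 cells, an immortalised mouse myoblast line. The cells carried a doxycycline-inducible, codon-altered transgene for either human DUX4 or mouse Dux, both double-homeodomain transcription factors. There were 5 samples with 1 library each. DUX4-expressing cells were precipitated with both DUX4 antibodies (MO488 and MO489) together, or with an antibody to the HA tag, which these cells lacked. Dux-expressing cells were precipitated with the Dux antibody A-19, with the Dux antibody S-20, or with control IgG. Doxycycline was given at 2 µg/ml. The labels' treatment protocol states 18 h of induction and the series design states 24 h, and the difference was not resolved. Per the labels' protocols, formaldehyde fixation (1%) lasted 11 min, chromatin was sheared to 150 to 600 bp, and libraries were sequenced as a 12-plex pool. The earlier DUX4 data from human myoblasts that the series design mentions were not analysed here.

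Reads were aligned with Subread to mm10, per the submitters' processing notes. Peaks were called with MACS2 version 2.1.0.20151222 at a q threshold of 0.01 with 1 tag kept per position, per the file headers, from 1 precipitated and 1 control library at a time, with no pooling. The HA library was the control for DUX4, and the same IgG library was the control for A-19 and S-20. The 3 lists were not made in the same way. Per the file headers, the DUX4 list was called on filtered alignments, by a filter the headers do not describe, and the A-19 and S-20 lists on sorted alignments with no such filter named. Each deposited list gives the position, length and summit of a peak. The deposited signal is the fragment pileup at the summit, with the larger library scaled to the smaller. The deposited fold enrichment is the ratio of that pileup to the local background estimated from the control library. The deposited −log10 p-values and −log10 q-values come from the same comparison in MACS2. Fold enrichments are the authors' own values and were used to describe, rank or filter peaks within a list.

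Depth was taken from the file headers. The DUX4 library had 23011031 tags, of which 20446330 were used after removal of redundant tags, and its HA control had 20505551 tags, of which 16668190 were used. The A-19 library had 18504661 tags (15250940 used), the S-20 library 17648888 (14639717 used) and the IgG control 18585374 (15385529 used). The fragment lengths used for calling were 205 bp for DUX4, 191 bp for A-19 and 164 bp for S-20. Intervals on shares of peaks are exact (Clopper-Pearson) 95% intervals and cover counting error only. Without replicate libraries no spread between cultures could be estimated, so each test compares peak positions in these lists and not conditions.

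Genes came from a RefSeq table of GRCm38.p6, whose coordinates are those of mm10, with 49980 genes on the assembled chromosomes and the mitochondrial genome, 21900 of them protein-coding. The table gives no strand, so distances were measured to either end of a gene in place of the transcription start that had been planned. Coordinates are 1-based, and exons and introns were not used here. A gene was counted as near a peak when a summit lay within 10 kb of either of its ends. No genome sequence was used here, so the planned tests of DUX4 and Dux sequence motifs, of enriched short sequences and of repeat-masked sequence were not run, and assembly gaps were not left out of random placements.

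Overlap was counted from 1 bp. Overlaps and distances to gene ends were compared with 1000 random placements of each peak on its own chromosome, between the lowest and highest position of any gene or peak. Overlap tests were one-sided, with 0.001 the smallest p the placements can give, and tests of gene ends were two-sided, with 0.002 the smallest. Benjamini-Hochberg adjustment was made over the 3 overlaps and over the 3 lists of distances. Fisher's exact test (two-sided) compared genes near peaks of both proteins. It also compared the members of 12 gene lists with all other protein-coding genes, adjusted over 36 tests. The lists were cleavage-stage genes, mouse members of gene families that DUX4 induces in human muscle cells, skeletal muscle, pluripotency, germline and meiosis, p53 and cell death, interferon and innate immune, nonsense-mediated decay, homeobox cluster, extracellular matrix and fibroblast, ribosomal protein and olfactory receptor genes. The first 2 of these lists shared 30 members. Neighbouring genes share peaks and are not independent, so these p-values are too small where a list is clustered.

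The rule for named genes was fixed before the data were examined. It takes the 10 protein-coding genes nearest to the strongest peaks of each list, up to 4 members of each gene list by fold enrichment, the 10 genes with the best combined rank among those near peaks of all 3 lists, and known targets of the family (Zscan4, Wfdc3, Zfp352 and Tcstv genes). Gene lists, main tests and most alternatives were also fixed before the data were examined. The alternatives were stricter q and fold thresholds, other definitions of overlap, other windows, local displacement of peaks by 5 to 50 kb, equal numbers of peaks, and counting neighbouring list members once. Copies of a gene were taken as genes whose symbols start with the same letters within 1 Mb, which also joins predicted genes named Gm that need not be copies. Tests of a gene list's difference between peak lists, random placement as a test of gene lists, and alternatives based on the implied control background, were added after the data were seen. That background is the pileup plus 1, divided by the fold enrichment, minus 1. Its lowest value matched the genome-wide level computed from library size within 0.02 for 58.5% of DUX4, 51.2% of A-19 and 49.8% of S-20 peaks, and no peak lay below that level.

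The procedures were tested on simulated data. With 20% overlap planted, the overlap of S-20 with A-19 peaks was recovered as 19.8%, that of A-19 with DUX4 peaks as 19.8% and that of S-20 with DUX4 peaks as 19.1%. Of 50 simulated lists without planted overlap, 2, 5 and 2 were called at 0.05. The 5 of 50 for A-19 with DUX4 peaks is above the nominal rate. For distances to gene ends, 0, 1 and 0 of 20 null lists were called for DUX4, A-19 and S-20. Of 200 simulated gene lists of 60 genes without an effect, 7, 8 and 5 were called for DUX4, A-19 and S-20. Lists with a planted effect were called in 65.5% of cases for DUX4 and 100% for A-19 and S-20. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.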

Results

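Human DUX4 and mouse Dux were each expressed from a doxycycline-inducible transgene in C2C12 mouse myoblasts, and their binding was mapped by ChIP-seq. The series design sets the human and the mouse protein side by side in mouse cells. DUX4 drives genes of the early embryo when it is expressed in human muscle, and Dux is its mouse relative, which is active at the 2-cell stage. Each of the 3 peak lists came from 1 precipitated library and 1 control library, with no replicates. Libraries held 17648888 (S-20) to 23011031 (DUX4) tags.

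The DUX4 list held 46136 peaks, 19.2 times as many as the 2400 of Dux antibody A-19 and 73.5 times the 628 of Dux antibody S-20. Peaks covered 13.3 Mb of mm10 for DUX4, 0.666 Mb for A-19 and 0.144 Mb for S-20. Median fold enrichment over the control was 7.85 for DUX4, 7.82 for A-19 and 7.88 for S-20, and the highest values were 59.2, 34.8 and 21.0. The lists differed in antibody, control library and alignment filter, so their lengths cannot be read as numbers of sites bound by each protein.

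The strongest DUX4 peaks near genes lay by Rtl9, a retrotransposon-derived gene (44.8-fold, 9732 bp from the gene), and by Tceal7 (39.0-fold, 4112 bp), both on chromosome X. Gsdmd, which encodes the pore-forming protein gasdermin D, followed at 33.1-fold, and Rnf11, Agxt2, Vwa8, Tsc22d2, Senp7, 3110040M04Rik and Tex48 lay between 32.1-fold and 29.8-fold. Of these 10 peaks, 5 lay inside the gene. The Rtl9 peak was at chromosome X, 143114719 to 143115293, and the Agxt2 peak at chromosome 15, 10410687 to 10411271, 788 bp beyond the gene.

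The strongest A-19 peaks near genes lay by Pramel45 (33.7-fold), a member of the Prame family that is active in germ cells and early embryos, and in Dbt (30.1-fold), which encodes a subunit of the branched-chain keto acid dehydrogenase. Gm46934 (27.4-fold) and Tmem131 followed, then Ergic2, Zscan4f and Psme3ip1 at 24.2-fold each, and Dact3 (23.8-fold), Fam171a1 (23.5-fold) and Nfib (22.6-fold). S-20 shared Dbt (19.3-fold), Pramel45 (18.8-fold), Gm46934 (15.8-fold), Ergic2 (14.0-fold) and Nfib (13.3-fold) among its own 10, beside Avpi1, Pramel41, Bnip1, Megf9 and Pramel18. The Pramel45 peak was at chromosome 5, 95106293 to 95106783 in the A-19 list and 95106334 to 95106685 in the S-20 list. The Dbt peak lay inside the gene at chromosome 3, 116521439 to 116521916 (A-19) and 116521520 to 116521892 (S-20).

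The 2 Dux antibodies marked largely the same places, as seen from the shorter list. Of the 628 S-20 peaks, 609 (97.0%, 95% exact interval 95.3 to 98.2%) overlapped an A-19 peak, against 0.0637% in random placements (permutation adjusted p = 0.001, the smallest possible). Conversely, 607 of 2400 A-19 peaks (25.3%) overlapped an S-20 peak. That share was 6.59% in the lowest quartile of A-19 fold enrichment and 63.0% in the highest. Summits of the 609 shared peaks were a median of 22 bp apart, and Spearman's rho of their fold enrichments was 0.595 across peaks, which are not independent replicates. Both lists were called against the same IgG library, so part of the overlap may come from that control, and this could not be separated without reads.

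DUX4 and Dux peaks coincided at few places, though more than random placement gave. Of 2400 A-19 peaks, 130 (5.42%, interval 4.55 to 6.40%) overlapped a DUX4 peak, 5.33 times the 1.02% of random placements. Of 628 S-20 peaks, 41 (6.53%, interval 4.73 to 8.75%) did, 6.94 times the 0.941% of random placements. For both the permutation adjusted p was 0.001, the smallest possible. These 130 A-19 peaks met 129 DUX4 peaks, 0.280% of the DUX4 list. Summits of the shared A-19 and DUX4 peaks were a median of 39.5 bp apart, and Spearman's rho of their fold enrichments was 0.0777. A-19 peaks with an S-20 peak met a DUX4 peak in 7.25% of cases and those without in 4.80% (odds ratio 1.55, Fisher's exact p = 0.0288). That comparison was not among the planned tests, and its p was not adjusted. From the lowest to the highest quartile of A-19 fold enrichment, 6.42%, 4.42%, 4.47% and 6.33% of A-19 peaks met a DUX4 peak, with no steady rise.

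**Figure D1:**
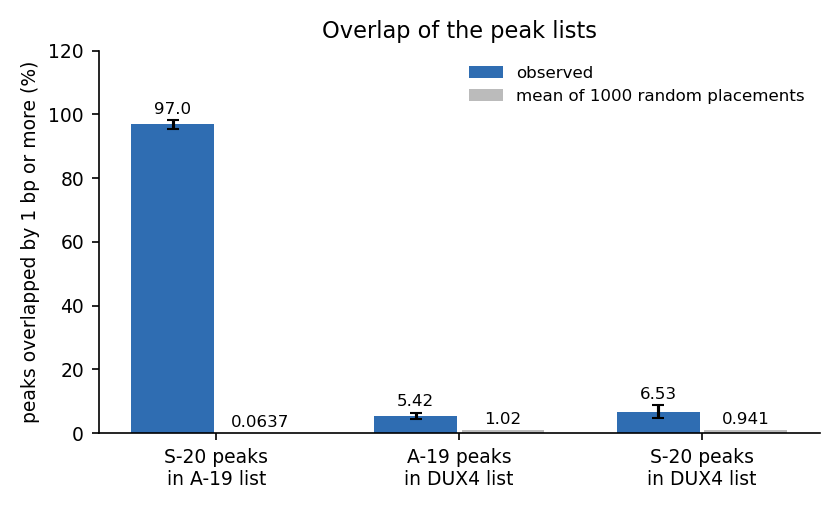
Share of peaks (percent, bars, with 95% exact binomial intervals) of the first list that overlapped a peak of the second by at least 1 bp, beside the mean of 1000 random placements (grey). S-20 peaks lay in the A-19 list at 97.0%, while A-19 and S-20 peaks lay in the DUX4 list at 5.42% and 6.53%.

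Genes near peaks of both proteins were more numerous than independent lists give. Within 10 kb of an end, 6762 protein-coding genes had a DUX4 peak, 686 an A-19 peak and 191 an S-20 peak. DUX4 and A-19 shared 270 genes, against 212 for independent lists (odds ratio 1.47, Fisher's exact p = 1.95e-06), and DUX4 and S-20 shared 90 against 59.0 (odds ratio 2.01, p = 2.75e-06). The DUX4 and A-19 result no longer passed with peaks of at least 10-fold (odds ratio 1.43, Fisher's exact p = 0.107). The DUX4 and S-20 result no longer passed with a window of 1 kb (Fisher's exact p = 0.112) or with as many DUX4 as A-19 peaks (p = 0.0748). With gene bodies included the odds ratios were 3.15 for A-19 (Fisher's exact p = 3.15e-82) and 3.86 for S-20 (p = 5.34e-33). Such windows grow with gene length in every list, so long genes can be shared without a link between the lists. These values therefore do not show stronger sharing. For A-19 the odds ratio was 2.94 with a window of 1 kb (Fisher's exact p = 0.00239). For S-20 it was 3.03 with peaks of at least 10-fold (Fisher's exact p = 0.0109). In all, 87 genes were near peaks of all 3 lists. The best-ranked of these were Dbt, Pramel45, Pramel18, Gm46934, Ythdc1 (a reader of methylated RNA), Mia3, Ctdspl2, Pramel41, Tdpoz3 and Gm6348. At 9 of these 10 genes the strongest DUX4 and A-19 peaks did not overlap. In Dbt the A-19 summit was at 116521699 inside the gene and the DUX4 summit at 116505854 outside it (14.3-fold). At Mia3 the DUX4 summit was at 183367212 on chromosome 1 (22.6-fold) and the A-19 summit at 183320877 (17.8-fold). At Tdpoz3 the summits coincided, at 93819669 for DUX4 (7.78-fold), 93819706 for A-19 (19.5-fold) and 93819721 for S-20 (12.6-fold) on chromosome 3.

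Zscan4 genes, which are expressed in the 2-cell embryo, had Dux peaks and no DUX4 peaks within 10 kb. All 9 Zscan4 genes and pseudogenes of the cluster on chromosome 7 had an A-19 peak and 8 had an S-20 peak, while 0 had a DUX4 peak. A-19 fold enrichment was 24.2 at Zscan4f, 19.2 at Zscan4c, 17.2 at Zscan4d and 7.55 at Zscan4b, and S-20 gave 13.1, 11.8, 7.88 and 5.83. Their A-19 summits lay 120, 211, 170 and 132 bp from the gene. In the region of 1.02 Mb from 10694241 to 11714112 there were 11 A-19 peaks against 0.905 at the genome's average density, 9 S-20 peaks against 0.237, and 8 DUX4 peaks against 17.4. At the lower density of chromosome 7, the expected numbers were 0.667, 0.239 and 9.99. DUX4 was expected to have 2.16 peaks near the 9 genes at the chromosome's density, so the depth of its list gives little power to show fewer (Poisson probability of 0 was 0.115). These copies are near-identical, and reads may have been assigned among them arbitrarily.

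**Figure D2:**
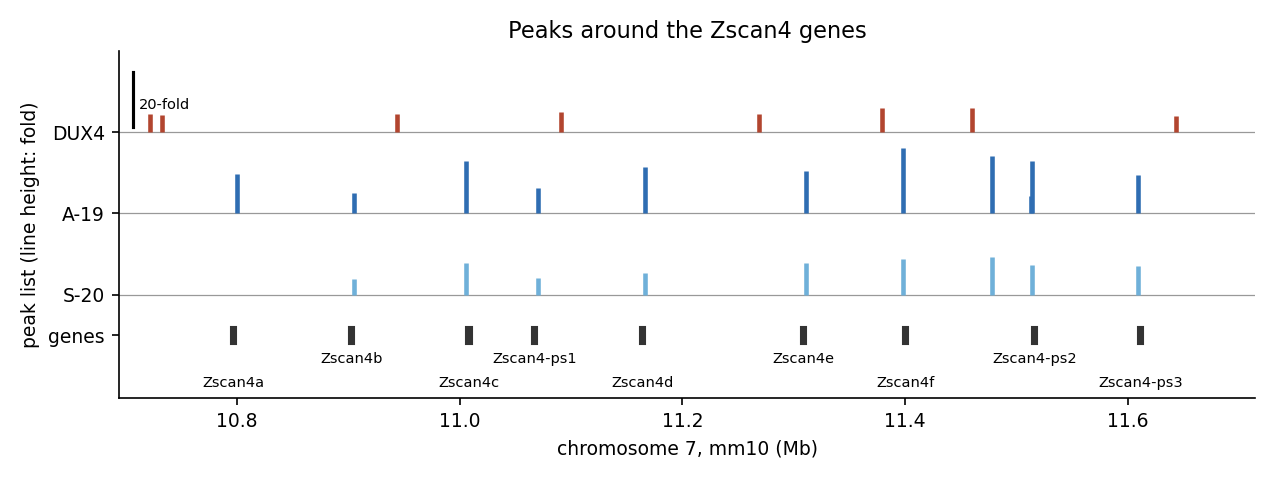
Map of chromosome 7 (mm10, Mb on the horizontal axis) around the Zscan4 genes, with vertical lines at peak summits whose height is the fold enrichment (scale bar 20-fold) and gene bodies as black boxes. A-19 peaks stood at all 9 genes and S-20 peaks at 8, and the 8 DUX4 peaks of the region lay more than 10 kb from any of them.

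Other multi-copy families of the early embryo varied in which lists had peaks near them. Among 6 Usp17l genes, which encode deubiquitinases, 3 had an A-19 peak (highest 11.5-fold, at Usp17le), 1 an S-20 peak and 0 a DUX4 peak. Among 8 Tdpoz genes 3 had A-19, 3 had S-20 and 5 had DUX4 peaks, and among 49 Prame-family genes 19, 8 and 29 did. Of 53 Obox genes, homeobox genes of the oocyte, 10 had A-19, 4 had S-20 and 27 had DUX4 peaks. Of 3 Trim43 genes, 1 had a DUX4 peak (3.92-fold) and 0 had a Dux peak. The 2 Tcstv genes and 3 Khdc1 genes had no peak in any list. Wfdc3 (6.70-fold) and Zfp352 (7.85-fold, 9909 bp away) had DUX4 peaks and no Dux peak. For comparison, 30.9% of protein-coding genes outside the cleavage-stage list had a DUX4 peak, 3.06% an A-19 peak and 0.838% an S-20 peak. DUX4 peaks were near 62.5% of Tdpoz, 59.2% of Prame-family and 50.9% of Obox genes, and near 0% of Zscan4 and Usp17l genes. The family counts cover genes of all types, and they were not tested by family.

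Cleavage-stage genes as a list were near Dux peaks more often than other genes. Of 68 matched members, 17 (25%) had an A-19 peak against 3.06% of other genes (odds ratio 10.5, Fisher's exact adjusted p = 8.07e-10), and 8 (11.8%) had an S-20 peak against 0.838% (odds ratio 15.8, adjusted p = 1.64e-06). For DUX4, 23 members (33.8%) did, against 30.9% (odds ratio 1.14, Fisher's exact adjusted p = 0.940), and its strongest were Duxbl3 (19.1-fold), a Dux-like gene, Gata2 (14.4-fold), Gm5662 (10.6-fold) and Tdpoz4 (10.2-fold). Without peaks of raised control background, the S-20 result no longer passed (odds ratio 6.29, Fisher's exact adjusted p = 0.0721, the highest over its 9 alternatives, with 1.17e-06 the lowest). The A-19 odds ratio was 32.8 with a window of 1 kb, 4.96 with 50 kb and 5.57 with gene bodies, and the S-20 odds ratio 48.7, 5.38 and 8.38, or 33.5 with peaks of at least 10-fold. Random placements of the peaks gave means of 1.57 members for A-19 and 0.405 for S-20 (permutation adjusted p = 0.018 for both). For mouse members of gene families that DUX4 induces in human muscle, 11 of 48 had an A-19 peak (odds ratio 9.33, Fisher's exact adjusted p = 1.86e-06), 5 an S-20 peak (odds ratio 13.5, adjusted p = 0.000435) and 14 a DUX4 peak (odds ratio 0.922, adjusted p = 1). With windows of 1 kb and 50 kb and with gene bodies, the A-19 odds ratio of this list was 29.9, 4.38 and 4.95, and that of S-20 was 70.9, 4.43 and 7.25. This list shares 30 members with the first, including the Zscan4 and Usp17l genes. Its strongest DUX4 peaks lay by Duxbl3, Siah1a (18.6-fold), Hspa2 (17.7-fold) and Rbbp6 (13.9-fold).

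**Figure D3:**
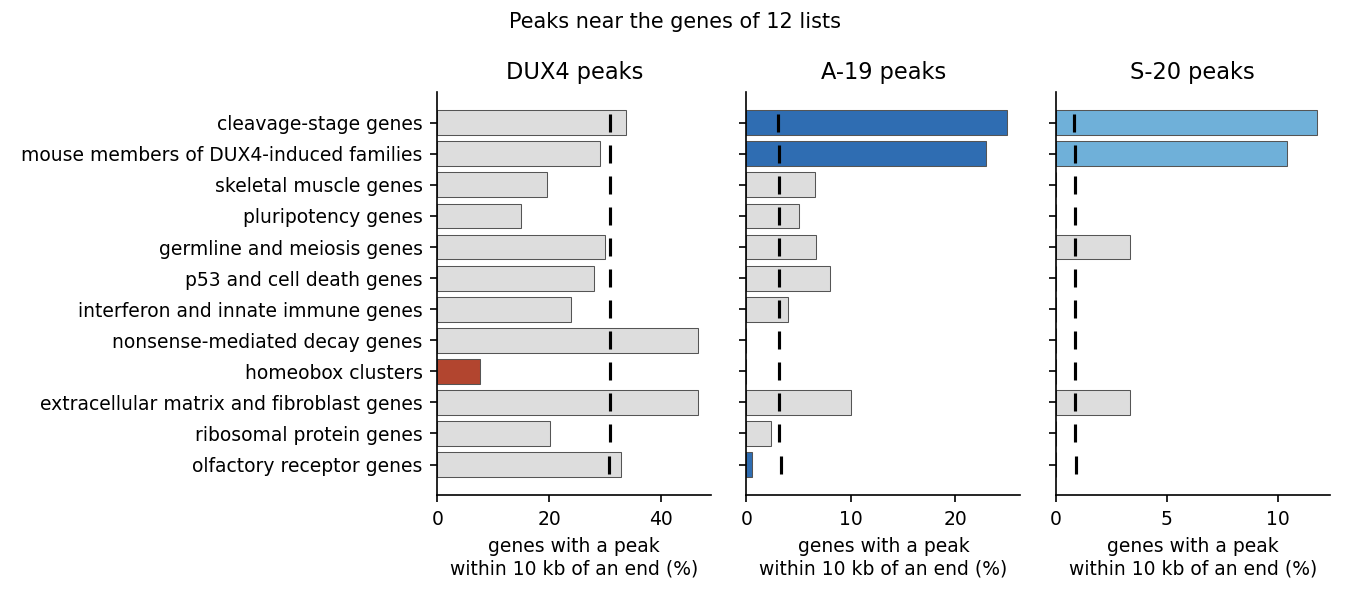
Percent of each gene list's members with a peak within 10 kb of an end (bars) and of all other protein-coding genes (black ticks), for DUX4, A-19 and S-20 peaks, with a separate percent axis for each. Coloured bars passed an adjusted p of 0.05 in Fisher's exact test, as did the olfactory receptor genes for S-20, where the bar is at 0.

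Olfactory receptor genes, silent in muscle, were near A-19 peaks in 6 of 1106 cases (odds ratio 0.161, Fisher's exact adjusted p = 2.75e-08) and near S-20 peaks in 0 of 1106 (adjusted p = 0.000507). For DUX4 they were near peaks in 363 cases (odds ratio 1.10, Fisher's exact adjusted p = 0.418), with the strongest at Olfr1359 and Olfr455. The DUX4 direction depended on the setting: the odds ratio was 0.687 with peaks of at least 10-fold (Fisher's exact adjusted p = 0.00971) and 0.394 with equal numbers of peaks (0.00738), but 1.64 with a window of 50 kb (3.68e-10). With gene bodies it was 0.685 (Fisher's exact adjusted p = 9.16e-08). That window grows with gene length, so the value also depends on the length of the genes and does not by itself show a change of direction. Random placements gave a mean of 309.9 genes for DUX4 (permutation adjusted p = 0.0206), 20.2 for A-19 (0.0206) and 5.52 for S-20 (0.0648). These genes form 84 clusters, of which 5 had an A-19 peak against a mean of 11.8 in random placements (permutation adjusted p = 0.0411), 0 an S-20 peak against 4.03 (0.0720) and 62 a DUX4 peak against 57.4 (0.523). With each cluster set against single genes, which favours the wider clusters, the odds ratio was 1.87 for A-19 (Fisher's exact adjusted p = 0.544) and 6.34 for DUX4 (2.62e-14). Over 9 alternatives the adjusted p ranged from 1.76e-20 to 0.931 for A-19, 7.62e-08 to 1 for S-20 and 2.62e-14 to 1 for DUX4. Homeobox cluster genes had a DUX4 peak in 3 of 39 cases, Hoxa4, Hoxa5 and Hoxa6, all from 1 peak of 6.99-fold (odds ratio 0.186, Fisher's exact adjusted p = 0.00411). The 39 genes form 4 clusters, of which 1 had a DUX4 peak against a mean of 3.55 in random placements (permutation adjusted p = 0.0411). Those placements take no account of DUX4 peaks lying far from gene ends in general. By Fisher's exact test the result did not pass with each cluster set against single genes (odds ratio 0.745, adjusted p = 1). Nor did it pass with peaks of at least 10-fold (Fisher's exact adjusted p = 0.219), a window of 1 kb (1) or equal numbers of peaks (1). In those settings the odds ratio was 0, with fewer genes near peaks to test. The lowest Fisher's exact adjusted p over 9 alternatives was 3.46e-05.

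The remaining lists did not pass Fisher's exact test at 10 kb. Skeletal muscle genes had DUX4 peaks at 9 of 46 members, led by Dmd (15.3-fold), which encodes dystrophin, Myl1 (12.8-fold), Neb and Myh8. Chrna1 (7.43-fold), Mef2d (7.38-fold) and Des (5.88-fold) had A-19 peaks, and 0 members had S-20 peaks. Extracellular matrix and fibroblast genes had DUX4 peaks at 14 of 30 members, including Pdgfra (17.7-fold), Sparc (15.5-fold), Col3a1 and Col6a2, and A-19 peaks at Tgfb2, Fbn1 and Lox. The S-20 list also had a peak at Fbn1 (8.73-fold). Of 25 p53 and cell death genes, 7 had DUX4 peaks, among them Mdm2 (14.9-fold), Ccng1, Casp8 and Trp53 (11.8-fold), and Pmaip1 and Fas had A-19 peaks. Ifit2 and Ifit3, interferon-induced genes, shared a DUX4 peak of 27.7-fold, and 6 of 25 interferon genes had one, including Cxcl10 and Eif2ak2, while Ifih1 had an A-19 peak (7.82-fold). Of 15 nonsense-mediated decay genes, 7 had DUX4 peaks, including Magohb, Magoh, Eif4a3 and Upf2, and 0 had Dux peaks. Of 30 germline genes, 9 had DUX4 peaks, led by Tex14 (14.9-fold) and Sycp1, and Nobox (16.0-fold) and Zp2 (13.3-fold) had A-19 peaks. Among 20 pluripotency genes, Tbx3 (12.8-fold), Klf5 and Tfcp2l1 had DUX4 peaks and Klf5 an A-19 peak. Of 84 ribosomal protein genes, 17 had DUX4 peaks, led by Rpl23a, and Rpl37 and Rps20 had A-19 peaks. The smallest adjusted p among these lists was 0.151, by Fisher's exact test, for ribosomal protein genes and DUX4. With a window of 50 kb, ribosomal protein genes (odds ratio 0.357, Fisher's exact adjusted p = 2.96e-05) and skeletal muscle genes (odds ratio 0.430, adjusted p = 0.0178) were near DUX4 peaks less often than other genes. Random placements at 10 kb gave more members near DUX4 peaks than the 9 muscle genes (mean 19.4, permutation adjusted p = 0.0206). The same held for the 17 ribosomal protein genes (mean 27.4, permutation adjusted p = 0.048). With clusters counted once the muscle genes passed (permutation adjusted p = 0.0411) and the ribosomal protein genes did not (0.063). Such placements take no account of DUX4 peaks lying far from gene ends in general, so they do not set these lists apart from other genes. Germline (9 against 13.5), p53 (7 against 10.7), interferon (6 against 9.71) and pluripotency genes (3 against 7.49) were also below the mean. None of these passed the threshold (permutation adjusted p = 0.382, 0.462, 0.4795 and 0.1505, in that order). Nonsense-mediated decay (7 against 6.51) and extracellular matrix genes (14 against 13.6) were not below the mean.

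Dux peaks lay nearer to gene ends than random placements and DUX4 peaks farther. Within 1 kb of an end of any gene lay 8.38% of A-19 summits against 6.20% by chance (permutation adjusted p = 0.003) and 8.76% of S-20 summits against 6.20% (adjusted p = 0.014). For DUX4 it was 3.94% against 6.08% (permutation adjusted p = 0.003). The median distance to a gene end was 23.0 kb for DUX4, 13.9 kb for A-19 and 13.0 kb for S-20, and 33.2%, 40.1% and 40.1% of summits lay inside protein-coding genes. The S-20 result no longer passed when peaks were displaced locally, by 5 to 50 kb (permutation p = 0.120), or with protein-coding genes alone (p = 0.212), in a range of 0.008 to 0.468 over 6 alternatives.

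Peak density differed between chromosomes. Chromosome 15 had the highest density in each list, with 27.9 DUX4, 1.91 A-19 and 0.712 S-20 peaks per Mb against genome averages of 17.1, 0.888 and 0.232. On chromosome 4 the density of A-19 peaks was 1.70 times and that of S-20 peaks 1.73 times the average, and that of DUX4 peaks 0.967 times. Chromosome X was at 1.37 times the average for DUX4, 0.535 times for A-19 and 0.555 times for S-20. The DUX4 list also had 2 peaks on chromosome Y and 7 on the mitochondrial genome, and the Dux lists had 0 on either.

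**Figure D4:**
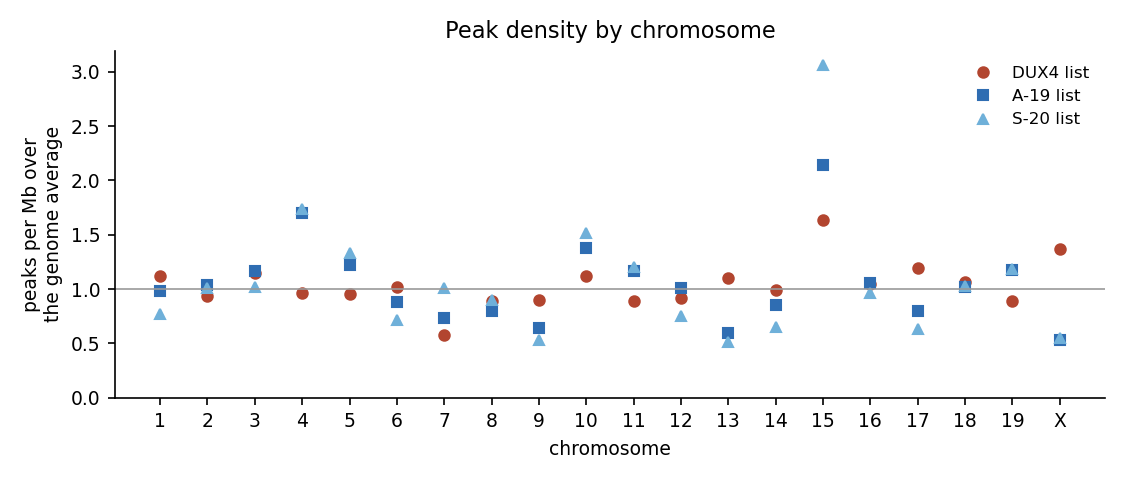
Peaks per Mb of each chromosome divided by the genome average of the same list (vertical axis, ratio), with 1 marked by a line, for the DUX4, A-19 and S-20 lists. Chromosome 15 was highest in each, at 1.63, 2.15 and 3.07 times the average, and chromosome X stood above 1 for DUX4 alone.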

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

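The tests of the difference between peak lists, with equal numbers of peaks for all but the cleavage-stage genes and A-19, were chosen after the results were seen, as were the technical tests that count neighbours once, look at the copies of named families, compare gene ends at equal numbers of peaks or relate density to background. That the windows of 100 kb decide nothing was also judged after their value was seen. Local displacement of peaks had been planned, and its use to weigh an explanation was chosen after the results were seen.

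Cleavage-stage genes and DUX4-induced families were represented differently near Dux and DUX4 peaks. Cleavage-stage genes made up a larger share of the genes near A-19 but not DUX4 peaks (11 of 416) than of those near DUX4 but not A-19 peaks (17 of 6492, odds ratio 10.3, Fisher's exact adjusted p = 3.36e-06). For S-20 the counts were 6 of 101 and 21 of 6672 (odds ratio 20.003, Fisher's exact adjusted p = 1.31e-05). For mouse members of DUX4-induced families, compared in the same way, the odds ratio was 11.9 for A-19 (Fisher's exact adjusted p = 1.17e-05) and 24.8 for S-20 (adjusted p = 3.16e-05). Of the family members with an A-19 peak, all but Zfp36l1 and Slc2a3 are also in the cleavage-stage list. All those with an S-20 peak are in it too, so these lists do not give separate results. Olfactory receptor genes differed the other way, with an odds ratio of 0.0413 for A-19 (1 of 416 and 358 of 6492 genes, Fisher's exact adjusted p = 1.05e-07) and of 0 for S-20 (0 of 101 and 363 of 6672 genes, adjusted p = 0.0255). With as many DUX4 peaks as the Dux list holds, the family difference was not past the threshold for A-19 (11 and 3 genes, odds ratio 2.55, Fisher's exact adjusted p = 0.602) or S-20 (5 and 0 genes, adjusted p = 0.602). The same held for the olfactory receptor difference for A-19 (6 and 10 genes, in 5 and 6 clusters, odds ratio 0.408, Fisher's exact adjusted p = 0.602) and S-20 (0 and 2 genes, adjusted p = 0.602). With all DUX4 peaks and neighbours counted once, the olfactory receptor difference passed for A-19 (odds ratio 0.0786, Fisher's exact adjusted p = 0.00137) and not for S-20 (adjusted p = 0.297). Summits within 1 kb of a gene end were more frequent in the A-19 than in the DUX4 list (odds ratio 2.23, Fisher's exact p = 3.48e-21) and in the S-20 than in the DUX4 list (odds ratio 2.34, p = 8.62e-08).

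For the cleavage-stage genes and A-19, the values argue against the greater length of the DUX4 list, taken alone. With as many of the strongest DUX4 peaks as A-19 peaks, the odds ratio was 12.0 (17 of 660 and 1 of 455 genes, Fisher's exact p = 0.00125, adjusted 0.0299). Peak strength was not matched by this, because the A-19 list kept its weaker peaks. The values also argue against repeated counting of neighbours within 100 kb, taken alone. With those counted once among members and other genes, the odds ratio was 5.53 (9 and 17 units, Fisher's exact p = 0.000255, adjusted 0.00153). The protein-coding Zscan4 genes lie more than 100 kb apart and stayed separate units, so repeated counting of these copies stays open. With equal numbers and neighbours counted once, 13 and 1 units gave an odds ratio of 10.0 (Fisher's exact p = 0.00544, adjusted 0.131). That was past the threshold only before adjustment. For S-20 at equal numbers, 8 and 0 genes in 7 and 0 clusters (Fisher's exact p = 0.0250, adjusted 0.300) were too few to decide. Copies of the Zscan4, Usp17l, Pramel and Tdpoz families were then taken within 1 Mb of copied members with an A-19 peak. These were parts of some families: 24 Pramel genes on chromosome 4 and 4 genes with symbols starting in Usp on chromosome 7, without Pramel45 on chromosome 5. Within 10 kb of these copies together, 24 DUX4 peaks stood against 16.2 expected from the surrounding 1 Mb (ratio 1.48, interval 0.924 to 2.27). The families went both ways and were not tested singly. DUX4 peaks numbered 0 against 2.95 expected for Zscan4 and 0 against 1.05 for Usp17l. They numbered 18 against 8.04 for Pramel and 6 against 3.85 for Tdpoz. Removal of reads at repeated copies by the DUX4 alignment filter therefore stays open. It stays open as well for the 13 members without a gene of the same name start nearby (odds ratio 5.33, Fisher's exact p = 0.216), and for the windows of 100 kb around copied members, where a criterion set beforehand was met (ratio 1.67, interval 1.21 to 2.26) but only 21.0% of the sequence was copies of these families. A difference in the sequences the 2 proteins bind stays open as an untested biological hypothesis, beside the different antibodies and controls.

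For distances to gene ends, the tables argue against regional placement as the whole cause for A-19 (permutation p = 0.008 with peaks displaced by 5 to 50 kb) and for DUX4 (p = 0.002), and leave it open for S-20 (p = 0.120). It may be part of the cause in each list, since the displaced means of 6.84% for A-19, 5.08% for DUX4 and 7.19% for S-20 lay between those of random placements (6.20%, 6.08% and 6.20%) and the observed 8.38%, 3.94% and 8.76%. They argue against list length, because as many of the strongest DUX4 peaks gave an odds ratio of 1.92 (201 A-19 and 109 DUX4 summits, Fisher's exact p = 7.46e-08). The DUX4 alignment filter and the HA and IgG controls go with the protein and cannot be told apart from it. A difference between the proteins may therefore be only 1 of several contributions, and it was not tested.

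For chromosome densities, extra chromosome copies in the cell lines are a candidate explanation in the Dux lists. Across 20 chromosomes, which are not independent replicates, density rose with the share of peaks whose background exceeded the genome-wide level, with Spearman's rho 0.598 for A-19 (permutation p = 0.00646, adjusted 0.0194) and 0.503 for S-20 (p = 0.0267, adjusted 0.0401). Pearson's r was 0.875 (permutation p = 3e-05) and 0.798 (p = 0.00034), and fell to 0.559 and 0.322 without chromosomes 15 and 4, so the relation rests largely on those. For DUX4 rho was 0.00301 (permutation p = 0.992) and r was 0.668 (p = 0.00627), or 0.156 without chromosomes 15 and 17. On chromosome 15 the share of peaks over the level was 91.9% for A-19, 93.2% for S-20 and also 75.2% for DUX4. On chromosome 4 it was 74.2% for A-19 and 77.8% for S-20 but 40.3% for DUX4. A difference in chromosome copies between the DUX4 and Dux cells was not tested and would go with the protein. On chromosome X of the DUX4 list 36.0% of peaks exceeded the level against 42.0% elsewhere (Fisher's exact p = 9.92e-14), the reverse of what extra copies were set to give. This does not decide the question. The 42.0% includes chromosomes 15 (75.2%) and 17 (55.4%), and peaks of 1 chromosome are not independent. Chromosomes 3 (35.4%), 7 (26.1%), 12 (34.6%) and 16 (35.1%) lay below X and the others above it. By rank the share was also unrelated to DUX4 density, so extra copies stay open there.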

How the results depend on the processing

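The alternatives based on the implied background, gene bodies and random placement of peaks, the DUX4 gene-end test and most list differences at equal numbers, and every alternative for genes shared by DUX4 and S-20 were chosen after the data were seen. Of 81 alternative values for the main results, 66 kept their direction and side of the threshold or stayed within 1.5 times the count. The cause of the changes below was not tested, except where fewer peaks were tested by construction.

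A fold enrichment of at least 10 left 11496 DUX4, 629 A-19 and 119 S-20 peaks. It ended the calls for S-20 near gene ends (8.40%) and for genes shared by DUX4 and A-19 (odds ratio 1.43). The S-20 call near gene ends was also lost with local displacement (8.76%), protein-coding genes (3.98%) and low background (8.36%). With as many DUX4 as S-20 peaks, the overlap of S-20 with DUX4 was 0%, which decides nothing because chance gave 0.0201%. With as many DUX4 as A-19 peaks, the share of A-19 peaks overlapped by DUX4 peaks was still past the threshold (0.375% against 0.0683%). For genes shared by DUX4 and S-20, the odds ratios of 1.96 with as many DUX4 as A-19 peaks and 2.72 with a window of 1 kb did not pass the threshold. Gene lists with fewer peaks numbered 0 with a window of 1 kb, 5 with 50 kb, 5 with gene bodies and 0 with neighbours counted once, against 3. Windows with gene bodies grow with gene length, so counts and odds ratios in that setting also depend on it. For olfactory receptor genes the DUX4 odds ratio turned to 0.687 at 10-fold, 0.394 at equal numbers and 0.685 with gene bodies, but passed the threshold above 1 with 50 kb (1.64), with neighbours counted once (6.34) and, as a ratio to random placements, at 1.17. The A-19 odds ratio turned to 1.87 with neighbours counted once, which by construction sets wide clusters against single genes. Motif, short-sequence and repeat alternatives were not run. No paired analysis was possible because each group had 1 library. How depth limits the lists was not tested.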

Other observations

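The comparisons of implied background and the choice of the genes named here were made after the results were seen. Duxf3, a double-homeobox gene, had a DUX4 peak (7.41-fold) and an A-19 peak (4.11-fold) within 10 kb and no S-20 peak. Tmem92 had an A-19 peak alone (7.04-fold).

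Peaks with a control background above 2 times the genome-wide level made up 4.97% of the DUX4, 5.38% of the A-19 and 10.5% of the S-20 list. Among A-19 peaks that met a DUX4 peak the share was 7.69%, against 5.24% of the others (Fisher's exact p = 0.228). Among the 19 S-20 peaks without an A-19 peak it was 15.8%, against 10.3% of the others (Fisher's exact p = 0.439).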
